A study of Mus musculus with 96 samples.

How the data were processed

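Messenger RNA was measured by RNA sequencing in 10 tissues of 4-month-old male mice on a mixed 129S6;C57Bl/6J background. The wild-type (WT) and Cyrano knockout (CyrKO) animals are compared here. Cyrano is a long noncoding RNA, listed in the annotation as Oip5os1, that is known to direct the decay of the microRNA miR-7. The tissues were anterior cortex, cortex, hippocampus, striatum with thalamus, cerebellum, pituitary, pancreatic islets, brown adipose tissue, skeletal muscle and spleen. Per the labels' protocols, tissue was snap frozen, RNA was taken up in Trizol, and poly(A) RNA was made into libraries that do not keep strand. Without strand, reads of a gene and of a transcript on the opposite strand at the same position cannot be told apart.

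The authors' deposited tables, 1 per tissue, hold raw read counts per gene for each library, with no normalization. Per the submitters' processing notes the tools were STAR 2.4, HTSeq 0.6.1p1 and DESeq2 1.10 and the genome build was GRCm38 (mm10); which annotation was used is not given in the sources used here. The same deposited tables give a log2 fold change per gene and its p-value and adjusted p-value from the authors' own comparison of CyrKO with WT. Those columns were used only for comparison with the tests run here.

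The labels describe 96 libraries and the deposited data have 95 count columns. The CyrKO spleen library without counts entered only the comparisons of values from the labels, RNA integrity and read number. Each library's group was taken from its labels. In skeletal muscle and spleen, 20 columns name the genotype but not which library they hold, so library numbers there only follow the order of the columns, and RNA integrity and replicate number could not be tied to them. The labels call the libraries biological replicates. They do not say whether libraries of different tissues came from the same animals.

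Total counts per library ranged from 2.18 to 17.2, in units of 1000000 counts, over 21777 genes. Replicates of a group differed by more than counting noise, with a chi-square per gene of 1.99 to 188 between pairs of libraries, so none were merged. In each tissue CyrKO was compared with WT in a fit of that tissue alone with edgeR 4.0.16 in R 4.3.3: TMM normalization, the default expression filter, quasi-likelihood F tests, and Benjamini-Hochberg adjustment over the 11474 to 13774 genes tested. A gene was called at an adjusted p under 0.05. Log2 fold changes are CyrKO over WT from that fit, and their standard errors come from the fold change and its F statistic. Levels are CPM, a gene's counts over the effective library total times 1000000, with SD over libraries. Differences between tissues were tested with the interaction of genotype and tissue in 1 edgeR model of all libraries, and between pairs of tissues for named genes.

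Positions, exons and untranslated regions (UTRs) came from the GENCODE M21 annotation of GRCm38, in which 21547 of the 21777 gene identifiers had a position. A miR-7 site is the 7-base word GTCTTCC in the longest annotated 3′ UTR, counted as an 8mer where A follows. An alternative used the shortest 3′ UTR of at least 50 bases where a gene had one. For each tissue the median log2 fold change of genes with a site was set against 10000 sets of the same size without a site, matched in 10 bins of expression and 10 bins of UTR length, among genes with a mean count of at least 20. The p-values are two-sided over genes, which are not replicates. The genotype labels were therefore also permuted exactly. Every 7-base word carried by at least 100 genes was also scored, after trends with expression, UTR length and GC content were removed, to rank the miR-7 word among all others.

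Gene lists written from general knowledge, 42 in all of which 41 could be tested, were tested with camera in limma 3.58.1 with a preset correlation of 0.01, and again with an estimated correlation. A list was tested in each tissue it was meant for in which at least 5 members had a mean count of at least 20. The adjustment covers all 179 pairs of list and tissue. Each list was also tested by exact permutation of the genotype labels on its mean log2 CPM per library (prior count of 2). Genes within 10 Mb of Oip5os1 were compared with all others by Fisher's exact test, two-sided. RNA integrity number (RIN) and read number, both from the labels, were compared between genotypes by exact permutation tests, two-sided.

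The main tests, the gene lists, the miR-7 site rule and the rule for named genes were fixed before the data were examined. The rule names Oip5os1 and the measured members of the noncoding RNA network list in each tissue. It names per tissue up to 6 called genes in each direction with a mean count of at least 50, up to 12 genes per direction called in at least 3 tissues, up to 6 called genes with a miR-7 site that fell, and up to 4 members of a gene list with the lowest p. Genes named outside this rule are said to be so where they appear. Alternatives were DESeq2 1.42.0, other filters and scalings, genes within 10 Mb left out, RIN as a covariate, the replicate number as a block, each library left out in turn, other site types and matchings, and other list tests.

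The edgeR fit per tissue, camera on 1 list, the miR-7 site test and word rank, and a later follow-up of choroid plexus genes were tried on simulated data. The other tests were not simulated. The data were made from the real genes' means and library sizes, for the edgeR fit with 200 changed genes per tissue, beside which up to 13 unchanged genes were called. In that setting edgeR recovered 23.9% to 76.1% of genes changed 1.5-fold, 65.7% to 94.0% of those changed 2-fold and 90.9% to 98.5% of those changed 4-fold, depending on the tissue, and called 0 genes when none were changed, while 4.55% to 5.11% of genes had an unadjusted p under 0.05. Simulated genes vary independently of each other, which real genes do not, so these shares are upper limits on power in that respect. With 200 changed genes the adjustment is also more lenient than where few genes change, so the shares overstate power for the real data. Cdr1 in cortex, for example, was 2.26-fold lower without passing (edgeR adjusted p = 0.31). Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for resampling and plots.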

Results

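The data compare 10 tissues of adult male mice that lack the long noncoding RNA Cyrano with the same tissues of wild-type mice. They hold 95 libraries, with 4 to 6 per genotype and tissue. Total counts per library are given in units of 1000000 counts. They were 8.03 to 17.2 in anterior cortex, 6.40 to 10.3 in cortex, 8.03 to 16.6 in hippocampus, 7.05 to 9.63 in striatum/thalamus and 7.47 to 13.4 in cerebellum. Pituitary had 6.21 to 9.48, islets 8.46 to 12.5, brown adipose tissue 7.63 to 13.2, skeletal muscle 2.18 to 10.3 and spleen 5.70 to 14.1. The 10 most abundant genes took up to 52.2% of a library's counts. The series title places the work in a network of regulatory noncoding RNAs in the brain. The question of each comparison is which transcripts change in a tissue when Cyrano is missing.

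Oip5os1, the Cyrano gene, fell in every one of the 10 tissues. In skeletal muscle, where it was most abundant, it went from 951 ± 101 CPM in WT to 11.4 ± 1.61 CPM in CyrKO (SD, n = 6 and 6), 81.8-fold lower. Its log2 fold change there was -6.35 ± 0.11 (SE; edgeR, Benjamini-Hochberg adjusted p = 8.1e-16). In the brain it was 27.6-fold lower in anterior cortex, 27.4-fold lower in cortex, 22.4-fold lower in hippocampus, 14.6-fold lower in striatum/thalamus and 12.2-fold lower in cerebellum. The WT levels in these regions were 553 ± 173, 554 ± 52.3, 414 ± 94.3, 369 ± 32.1 and 725 ± 169 CPM. Brown adipose tissue went from 271 ± 65.2 to 30.3 ± 8.02 CPM (n = 5 and 5) and spleen from 259 ± 35.1 to 52.6 ± 9.01 CPM (n = 4 and 4). Islets went from 37.5 ± 3.91 to 6.76 ± 1.56 CPM (n = 4 and 4), 5.42-fold lower. The smallest relative loss was in pituitary, from 92.2 ± 14.8 to 31.8 ± 4.77 CPM (n = 5 and 4), 2.90-fold lower (edgeR, Benjamini-Hochberg adjusted p = 0.0021). In the other 8 tissues the edgeR adjusted p lay between 1.2e-12 and 8.6e-05. Oip5os1 (ENSMUSG00000085438) is annotated as a lincRNA on the plus strand of GRCm38 chromosome 2, 119594297 to 119607502. Counts over the gene did not reach 0 in any CyrKO group, and they include any read from the opposite strand.

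**Figure D1:**
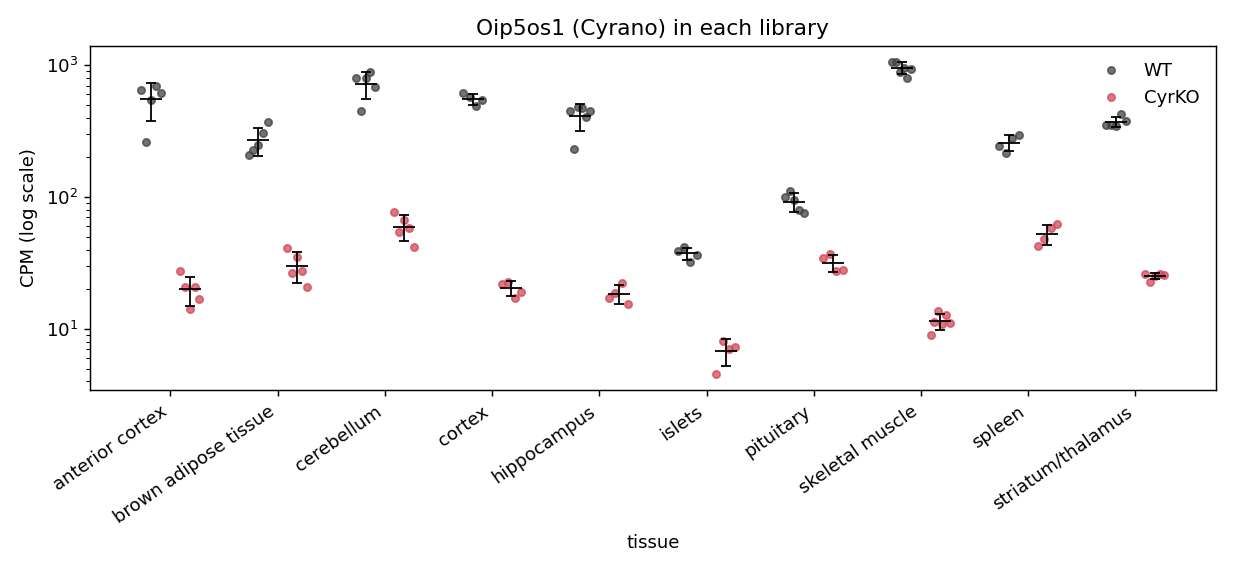
Oip5os1 in CPM (log axis) for each library, by tissue, with WT libraries in grey and CyrKO libraries in red; black bars are the mean and SD of a group. In skeletal muscle the groups lie at 951 and 11.4 CPM, and in pituitary, where they are closest, at 92.2 and 31.8 CPM.

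Nusap1, which encodes a microtubule-binding protein of the mitotic spindle and lies next to the Cyrano locus, rose in 5 tissues. In brown adipose tissue it went from 1.53 ± 0.43 CPM in WT to 85.1 ± 13.1 CPM in CyrKO (SD, n = 5 and 5), 55.6-fold higher (log2 fold change 5.80 ± 0.19; edgeR, Benjamini-Hochberg adjusted p = 1.4e-08). In skeletal muscle it went from 1.28 ± 0.44 to 61.7 ± 8.22 CPM (n = 6 and 6), 47.3-fold higher (5.56 ± 0.16; edgeR adjusted p = 9.1e-13). It rose 4.03-fold in cortex, from 3.76 ± 0.55 to 15.2 ± 1.71 CPM (n = 4 and 4), and 4.39-fold in striatum/thalamus, from 4.46 ± 1.002 to 19.5 ± 1.89 CPM (n = 5 and 5). In hippocampus it rose 3.15-fold, from 4.65 ± 1.98 to 14.7 ± 1.90 CPM (n = 6 and 4). The edgeR adjusted p in these 3 regions were 3.5e-05, 8.6e-06 and 0.0079. It did not pass in anterior cortex (4.96 ± 2.97 to 13.9 ± 2.27 CPM, edgeR adjusted p = 0.38), cerebellum (7.52 ± 3.70 to 16.8 ± 3.16 CPM, 1.0) or pituitary (4.27 ± 1.34 to 11.2 ± 1.53 CPM, 0.17). Nor did it pass in islets (1.05 ± 0.52 to 3.43 ± 0.38 CPM, 0.98) or in spleen, the tissue with the most Nusap1 in WT (72.1 ± 25.7 to 81.1 ± 10.6 CPM, 0.90). Without WT library 2, Nusap1 also passed in anterior cortex (8.6e-04), cerebellum (0.042) and pituitary (0.019). WT library 2 of anterior cortex was also low in Oip5os1 (8.02 log2 CPM, against 9.09 to 9.45 in the other WT libraries). DESeq2 called it in anterior cortex (9.2e-04), islets (0.043) and pituitary (1.8e-05).

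Nusap1 (ENSMUSG00000027306) lies on the plus strand at 119618298 to 119651244, 10795 bases beyond the end of Oip5os1. Between them, on the opposite strand, is Oip5 (ENSMUSG00000072980, 119609512 to 119618469), a centromere protein gene. It begins 2009 bases beyond Oip5os1, and its annotated span overlaps the start of Nusap1. In brown adipose tissue Oip5 went from 0.182 ± 0.167 to 2.49 ± 0.64 CPM (SD, n = 5 and 5), 13.2-fold higher (log2 fold change 3.72 ± 0.50; edgeR, Benjamini-Hochberg adjusted p = 0.034). It did not pass in the other tissues where it was tested, cerebellum (0.70 to 1.42 CPM, edgeR adjusted p = 1.0) and spleen (8.03 to 7.67 CPM, 0.96). In skeletal muscle edgeR's filter left it untested. DESeq2 (log2 fold change 3.10, adjusted p = 0.020) and the authors' deposited table (3.10, 0.020) call it higher there, and edgeR without the filter did not (3.03, 0.16). The call in brown adipose tissue rests on few counts and ended with RIN as a covariate (0.061). It also ended without WT libraries 3 (0.14), 4 (0.14) or 5 (0.18) or CyrKO libraries 1 (0.068), 2 (0.10), 3 (0.0503), 4 (0.15) or 5 (0.13). Chp1, Ndufaf1, Rtf1 and Exd1, also near the locus, were not called in any tissue by edgeR. In skeletal muscle, for example, Chp1, which codes for a calcium-binding protein, was at 75.2 CPM in WT and 77.3 CPM in CyrKO.

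**Figure D2:**
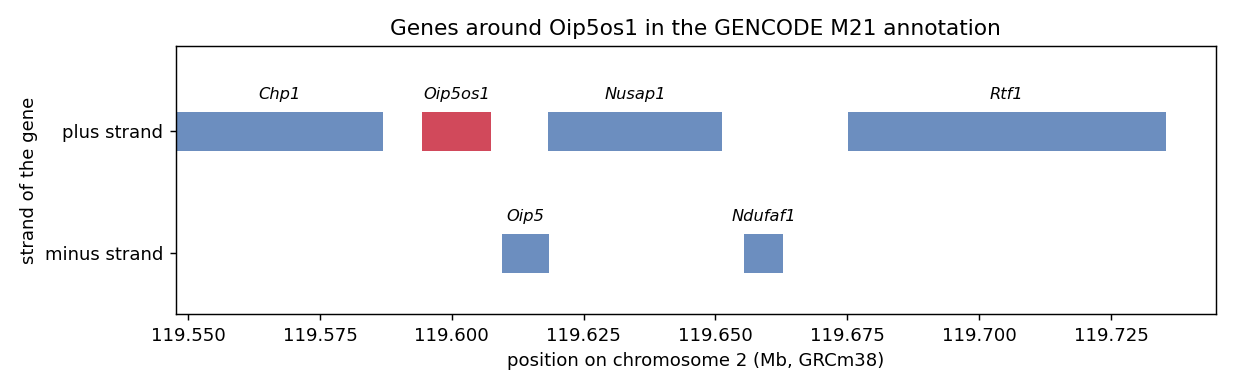
Genes around Oip5os1 on chromosome 2 of GRCm38 (position in Mb), drawn to scale by strand. Oip5os1 and Nusap1 are on the plus strand, with Oip5 between them on the minus strand.

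**Figure D3:**
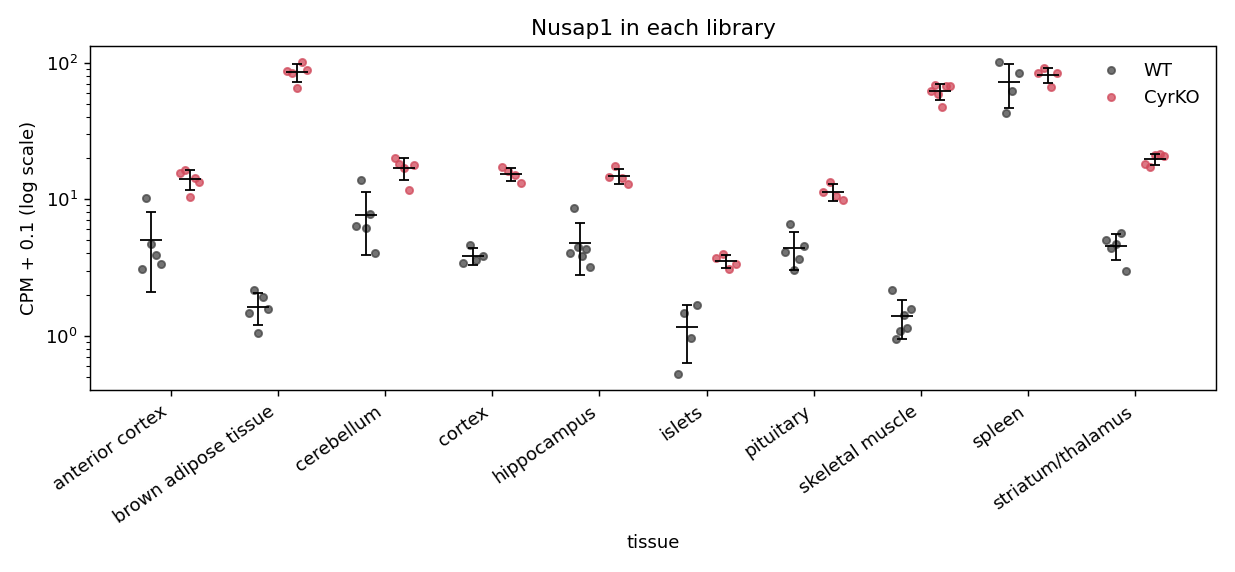
Nusap1 in CPM plus 0.1 (log axis) for each library, by tissue, with WT in grey, CyrKO in red and black bars for the mean and SD. The groups are farthest apart in brown adipose tissue (1.53 and 85.1 CPM) and skeletal muscle (1.28 and 61.7 CPM) and overlap in spleen (72.1 and 81.1 CPM).

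Nrep, which encodes a small protein expressed in regenerating neurons, fell in skeletal muscle. It went from 162 ± 25.7 to 87.9 ± 8.07 CPM (SD, n = 6 and 6), 1.85-fold lower (log2 fold change -0.89 ± 0.10; edgeR, Benjamini-Hochberg adjusted p = 5.7e-04). It was also lower, without passing, in brown adipose tissue (19.4 to 10.7 CPM, edgeR adjusted p = 0.51) and spleen (8.29 to 5.74 CPM, 0.87). In cerebellum, where it was most abundant, it was at 875 CPM in WT and 802 CPM in CyrKO (log2 fold change -0.13). The change in muscle differed from that in 7 other tissues by -0.72 to -1.09 on the log2 scale (edgeR interaction, Benjamini-Hochberg over 29 pairs, adjusted p of 0.0058 or lower). It did not differ detectably from that in brown adipose tissue (-0.04, adjusted p = 0.889 in edgeR) or spleen (-0.31, 0.337). Nrep (ENSMUSG00000042834, minus strand of chromosome 18, 33437019 to 33464029) has a miR-7 8mer in its last exon, exon 5 of 5. The site is at bases 280 to 286 of a 3′ UTR of 1695 bases (33438428 to 33438434). The sequence around it reads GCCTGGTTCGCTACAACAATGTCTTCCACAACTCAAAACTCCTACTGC.

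Cdr1, a single-exon gene whose opposite strand gives rise to a circular RNA rich in miR-7 sites, fell in cerebellum. It went from 46.0 ± 20.7 to 8.18 ± 2.95 CPM (SD, n = 5 and 5), 5.61-fold lower (log2 fold change -2.49 ± 0.34; edgeR, Benjamini-Hochberg adjusted p = 0.038). In cortex it was at 26.8 ± 6.26 CPM in WT and 12 ± 3.69 CPM in CyrKO without passing by edgeR (n = 4 and 4, adjusted p = 0.31), whereas DESeq2 (8.0e-05) and the authors' deposited table (8.05e-05) call it there. It was also lower in striatum/thalamus (15.4 ± 4.76 to 8.57 ± 1.98 CPM) and hippocampus (12.5 ± 2.54 to 7.40 ± 2.99 CPM), and closer to WT in anterior cortex (14.7 to 11.4 CPM). In pituitary it was at 1.66 CPM in WT and 2.59 CPM in CyrKO. The effect on Cdr1 did not pass an edgeR interaction over the 10 tissues (adjusted p = 0.175). In pairs tested because it was called in cerebellum, the log2 change there differed from that in anterior cortex by -2.10 (edgeR interaction, Benjamini-Hochberg adjusted p = 1.2e-04) and from that in cortex by -1.33 (0.015). It differed from that in hippocampus by -1.73 (0.0017) and from that in striatum/thalamus by -1.65 (0.0022). Cdr1 (ENSMUSG00000090546) is on the minus strand of chromosome X, 61184005 to 61185558. Unstranded reads of linear Cdr1 and of its antisense transcript fall on the same bases, so these counts do not separate them, and poly(A) selection leaves out most circular RNA. The cerebellum call, near the threshold, ended without WT libraries 1 (0.14), 2 (0.096), 3 (0.051) or 4 (0.083) or CyrKO libraries 1 (0.084), 2 (0.12), 3 (0.19), 4 (0.20) or 5 (0.078). It also ended with RIN as a covariate (0.42) and with genes within 10 Mb of Oip5os1 left out of the adjustment (0.076). Over the libraries left out the log2 fold change stayed between -2.69 and -2.27, and DESeq2 gave an adjusted p of 6.7e-06. In cortex, leaving out CyrKO library 2 brought Cdr1 to an edgeR adjusted p of 0.0499.

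The other measured members of the noncoding RNA network list did not pass. Hnrnpk, an RNA-binding protein gene that hosts a miR-7 precursor, had log2 fold changes from -0.19 in skeletal muscle to 0.06 in spleen (edgeR adjusted p of 0.64 or higher in the 10 tissues). Chpf2, a chondroitin polymerizing factor that hosts miR-671, ranged from -0.30 in skeletal muscle to 0.18 in spleen (0.72 or higher).

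Few genes passed beyond Oip5os1 in any tissue. Summed over tissues, edgeR called 18 changes, of which 10 were Oip5os1, 5 Nusap1 and 1 each Oip5, Nrep and Cdr1. The genes that rose and fell numbered 2 and 1 in brown adipose tissue, 1 and 2 in skeletal muscle and 0 and 2 in cerebellum. They numbered 1 and 1 in cortex, hippocampus and striatum/thalamus, and 0 and 1 in anterior cortex, islets, pituitary and spleen. Before adjustment, 307 (cerebellum) to 1141 (brown adipose tissue) genes per tissue had an edgeR p under 0.05. DESeq2 called 37 genes in anterior cortex, 63 in brown adipose tissue and 15 in spleen, and 2 to 6 elsewhere. The authors' deposited table calls 37, 55 and 13 genes in those 3 tissues and 128 over all tissues, including the 18. With Oip5os1 left out before adjustment, an alternative added after seeing the data, edgeR called 1 gene in brown adipose tissue, 0 in cerebellum and 2 in skeletal muscle, so the calls of Oip5 and Cdr1 ended. Fold changes correlated at 0.998 or more across genes with those of the authors' deposited table. Leaving out WT library 1 gave 7 genes in anterior cortex, 18 in islets and 6 in skeletal muscle. In anterior cortex 3 genes passed without WT library 3 and 2 without WT library 2, and in islets 2 without CyrKO library 1. In spleen 6 passed without WT library 3 and 5 without CyrKO library 4. Without WT library 3, 4 passed in hippocampus and in striatum/thalamus, and without WT library 2, 2 passed in pituitary.

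The genes named next are called in the authors' deposited table and not by edgeR, and were chosen after their values were seen. EdgeR's expression filter left Ngp and Ltf untested, and the others had an edgeR adjusted p of 0.19 to 0.87. All 13 calls in spleen in the authors' deposited table are lower in CyrKO. They include, with log2 fold changes from the authors' deposited table, the ribonuclease gene Ear6 (-3.27, adjusted p = 4.0e-05), the proteoglycan gene Prg2 (-1.57, 8.4e-05) and the peroxidase gene Epx (-2.48, 0.030). The lipoxygenase Alox15 (-1.80) and the resistin-like gene Retnlg (-1.67, 0.0024) are also among them in the authors' deposited table. In brown adipose tissue, the authors' deposited table lists the paraoxonase Pon1 (-1.83, 2.5e-05), the metal-binding protein genes Mt1 (-0.83, 6.9e-05) and Mt2 (-1.17) and the nicotinamide methyltransferase Nnmt (-1.37) as lower. It lists the deacetylase Hdac11 (1.56) as higher in the authors' deposited table. In anterior cortex, 27 of the 37 calls in the authors' deposited table are higher. Among them in the authors' deposited table are Ngp (3.64, 8.7e-04), the lactoferrin gene Ltf (2.88, 0.0062) and the calprotectin subunit S100a8 (2.46, 0.019). The transcription factor Rorb (-0.64, 0.013) and the clock gene Ciart (-0.75, 0.028) are lower in the authors' deposited table.

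The effect of the knockout was also compared between tissues. Of 16257 genes, 80 had an effect that differed between the 10 tissues at an adjusted p under 0.05 (edgeR interaction, Benjamini-Hochberg). Oip5os1 (F = 56.6, adjusted p = 3.3e-27 in edgeR), Nusap1 (53.8, 9.6e-27), Oip5 (7.44, 2.4e-04) and Nrep (4.74, 0.020) were among them, whereas Cdr1 was not (3.37, 0.175). Nusap1 rose more in skeletal muscle than in each of the 8 tissues other than brown adipose tissue, by 3.43 to 5.40 on the log2 scale. It rose more in brown adipose tissue than in the same 8, by 3.65 to 5.62. Some of the 80, named after their values were seen, are markers of cell types or regions that the gene lists also cover. They include the striatal receptors Adora2a and Drd1a, the choroid plexus channel gene Clic6 and the neutrophil genes S100a8, S100a9, Ltf and Retnlg. Such effects can rest on few libraries: the log2 fold change of Clic6 in hippocampus was 4.62, and 1.16 without CyrKO library 2.

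The genes called near Cyrano were Oip5os1 itself and its neighbours Nusap1 and Oip5. Within 10 Mb of Oip5os1, 3 of 138 tested genes changed in brown adipose tissue (Oip5os1, Nusap1 and Oip5), against 0 of 11871 elsewhere (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted p = 1.5e-05). In that tissue 1141 genes had an unadjusted edgeR p under 0.05 and DESeq2 called 63. Counting Oip5os1, Fisher's exact test passed in each of the 10 tissues with an adjusted p of 0.025 or lower. Oip5os1, the deleted gene, lies at the locus by definition, so its call alone gave that pass in anterior cortex, cerebellum, islets, pituitary and spleen. Oip5os1 was left out in an alternative added after seeing the data. Nusap1 and Oip5 then still made 2 of 137 in brown adipose tissue (0.0013), and Nusap1 alone made 1 in cortex, hippocampus and striatum/thalamus (0.030 each) and in skeletal muscle (0.047). In the other 5 tissues edgeR called 0 near genes besides Oip5os1 (1.0). In the union over tissues, 3 of 190 near genes and 2 of 15831 far genes, Nrep and Cdr1, changed (Fisher's exact test p = 1.6e-05). Without Oip5os1 it was 2 of 189 near genes (Fisher's exact test p = 8.2e-04). Without Nusap1 and Oip5 also, near genes were not detectably more often at an unadjusted p under 0.05 than others. The odds ratio ranged from 0.486 in spleen to 1.61 in pituitary (Fisher's exact test, Benjamini-Hochberg adjusted p of 0.592 or higher). This form was chosen after seeing the data, and its intervals are wide.

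Across tissues, Oip5os1 fell in 10 and Nusap1 rose in 5, and these were the genes edgeR called in the same direction in at least 2 tissues. If the lists of the tissues were independent, 0.00586 shared calls would be expected, summed over the 45 pairs. That sum counts pairs of tissues and not genes. Oip5os1, as the deleted gene, was bound to be shared, so its sharing is no test of independence. Across genes, which are not independent replicates, log2 fold changes of 2 tissues were weakly correlated without Oip5os1. The median Pearson r over the 45 pairs was 0.09 (-0.12 to 0.25) and the median Spearman rho 0.09. The 10 pairs of brain regions had a median r of 0.16, and the others 0.086. The labels do not say whether tissues came from the same animals, so this similarity is described and not tested.

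Genes with a miR-7 site in the 3′ UTR, the targets that more miR-7 would lower, were slightly lower than matched genes in 5 tissues. In skeletal muscle the median log2 fold change of 1528 site genes differed from that of matched sets by -0.016. The difference was -0.026 in spleen (1737 genes), -0.018 in brown adipose tissue (1603), -0.013 in striatum/thalamus (1883) and -0.011 in hippocampus (1861). Resampling over genes gave adjusted p of 0.0008 in brown adipose tissue and 0.0005 in the other 4 tissues (two-sided). The latter come from an unadjusted 0.0002, the smallest that 10000 sets can give. In spleen and brown adipose tissue the site genes themselves had medians above 0, at 0.044 and 0.0013, and lay below their matched sets at 0.070 and 0.019. The differences in anterior cortex (0.0086, adjusted p = 0.080), cerebellum (0.0024, 0.40), cortex (-0.0037, 0.12), islets (-0.0046, 0.28) and pituitary (0.0055, 0.12) did not pass. Genes are not replicates, and exact permutation of the genotype labels, two-sided, gave higher p. It gave 0.082 in skeletal muscle, 0.37 in spleen, 0.087 in brown adipose tissue, 0.29 in hippocampus and 0.024 in striatum/thalamus, where the value adjusted over 10 tissues was 0.24. Matched on expression alone, without UTR length, the difference turned positive in brown adipose tissue (0.0065), hippocampus (0.0019) and spleen (0.031, where it passed over genes with an adjusted p of 0.0004), and was -0.034 in skeletal muscle and -0.0048 in striatum/thalamus. Matched on GC content also, it was -0.0136 in spleen and -0.0064 in striatum/thalamus. Without CyrKO library 1 the shift in brown adipose tissue was -0.0137 (adjusted p = 0.080 over genes), and without CyrKO library 3 that in hippocampus was -0.0031 (0.33).

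**Figure D4:**
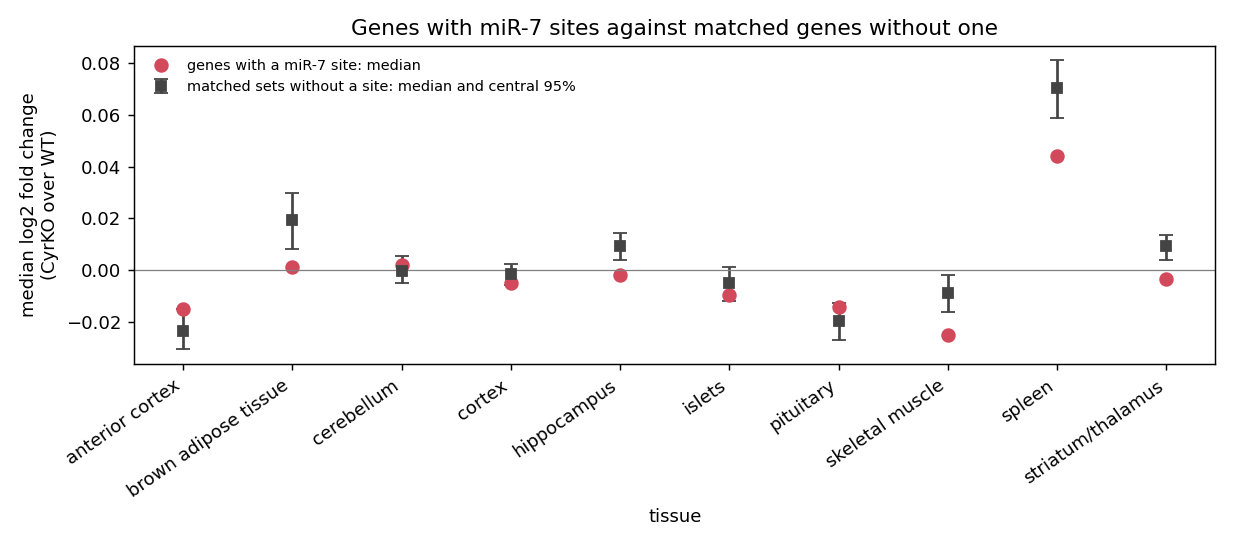
Median log2 fold change (CyrKO over WT) of genes with a miR-7 site (red) and of matched gene sets without a site (grey squares, with the central 95% of 10000 sets), by tissue. The red point lies below the grey interval in brown adipose tissue, hippocampus, skeletal muscle, spleen and striatum/thalamus.

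Among the 7-base words scored in 3′ UTRs, GTCTTCC ranked 1 of 15564 for lower expression in skeletal muscle and 2 of 15856 in striatum/thalamus. It ranked 8 in islets, 10 in spleen, 13 in brown adipose tissue and 96 in hippocampus, but 4811 in anterior cortex and 6035 in pituitary. Of the genes edgeR called, those with a site are Nrep, which fell in muscle, and Nusap1, which rose. The Nusap1 site, also an 8mer, is in exon 10 of 10 at bases 870 to 876 of a 3′ UTR of 2255 bases (chromosome 2, 119649859 to 119649865). It lies within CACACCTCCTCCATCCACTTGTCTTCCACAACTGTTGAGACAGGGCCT. The list of miR-7 targets from the literature, with members such as Irs2, was not called by camera in any of the 10 tissues (adjusted p from 0.149 to 0.978). Lower members numbered 8 of 22 in spleen, 9 of 20 in skeletal muscle, 10 of 23 in pituitary, 10 of 21 in brown adipose tissue and 12 of 24 in cerebellum. They numbered 14 of 22 in islets, 15 of 24 in anterior cortex and in cortex, 17 of 24 in hippocampus and 18 of 24 in striatum/thalamus. By edgeR 0 members were called over all genes or adjusted over the list alone, with up to 3 per tissue at an unadjusted p under 0.05, and DESeq2 called 0.

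Gene lists moved together in several tissues by camera with its preset correlation. Of 179 pairs of list and tissue, 38 were called. With an estimated correlation camera called 0 (lowest adjusted p = 0.755 with an estimated correlation). By exact permutation of genotype labels 0 passed, with 12 at an unadjusted p under 0.05 and a lowest adjusted p of 0.387. No list could pass that test alone over 179 pairs, since even skeletal muscle has only 924 divisions of its labels. Leaving out each library in turn, added after seeing the data, kept 14 of the 38 calls and ended the other 24 in at least 1 case. The calls most often shared were heat shock genes, higher in 6 tissues, and immediate early and interferon response genes, each higher in 4. Of the members of these called lists, edgeR over all genes called 1, Nusap1 in brown adipose tissue. DESeq2 called 5, which were Nusap1 and Oip5 there, Dlx1 in anterior cortex, and Retnlg and Ly6c2 in spleen. The counts of called list members are otherwise those adjusted over the list alone.

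Heat shock chaperone genes were higher in skeletal muscle and striatum/thalamus, and these calls were kept without each library. In skeletal muscle 11 of 11 members were higher, 2 of them called adjusted over the list alone. These were Hsph1, a co-chaperone of the Hsp110 family (121 ± 19.9 to 166 ± 27.9 CPM, SD, n = 6 and 6), and the small heat shock protein gene Hspb1 (22.3 to 33.1 CPM). The list median was 0.17 (camera adjusted p = 8.8e-04; adjusted p = 0.755 with an estimated correlation; exact permutation p = 0.024), and 0.26 without CyrKO library 1. In striatum/thalamus 11 of 12 were higher, with Hsph1 at 335 CPM in WT and 405 CPM in CyrKO. The median there was 0.17 (camera adjusted p = 5.5e-04; adjusted p = 0.755 with an estimated correlation), and 0.07 without CyrKO library 2, the library highest in striatum marker genes (7.18 log2 CPM). The list was also called higher in cerebellum (11 of 12, median 0.18), hippocampus (8 of 12, 0.21), islets (7 of 10, 0.18) and spleen (11 of 12, 0.25). These had adjusted p of 0.755 to 0.776 with an estimated correlation. Over the libraries left out, the median ranged from 0.06 to 0.26 in cerebellum and from 0.10 to 0.23 in hippocampus. In islets it ranged from 0.14 to 0.22 and in spleen from 0.16 to 0.37. The call ended in cerebellum without CyrKO library 4 (camera adjusted p = 0.067), in islets without CyrKO library 2 (0.097), and in spleen without WT library 3 (0.29) or CyrKO libraries 3 (0.17) or 4 (0.057). In hippocampus it ended without WT libraries 1 (0.0501) or 3 (0.070) or CyrKO libraries 2 (0.25), which was highest in choroid plexus genes (7.10 log2 CPM), or 4 (0.075).

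Immediate early genes, which neurons switch on with activity, were called higher in 4 brain tissues. They were higher for 22 of 23 members in anterior cortex (median 0.32), 16 of 20 in cerebellum (0.27), 20 of 23 in hippocampus (0.18) and 21 of 22 in striatum/thalamus (0.25). The adjusted p were 0.761 to 0.895 with an estimated correlation. Examples are the neuronal pentraxin Nptx2 in anterior cortex (68.1 ± 7.97 to 90.6 ± 18.6 CPM, SD, n = 5 and 5) and the synaptic regulator Arc in hippocampus (110 to 158 CPM, n = 6 and 4). By edgeR 0 members were called over all genes or adjusted over the list alone, with 1 or 2 per tissue at an unadjusted p under 0.05. In anterior cortex the call ended without WT library 5 (camera adjusted p = 0.13) or CyrKO library 4 (0.13). The median there ranged from 0.11 to 0.46 over the libraries left out, and was 0.16 without WT library 4. In cerebellum it ended without WT library 4 (0.051), and the median was 0.15 without CyrKO library 4. In hippocampus it ended without WT library 4 (0.067) or CyrKO libraries 2 (0.074; choroid plexus genes at 7.10 log2 CPM) or 4 (0.16), and in striatum/thalamus without WT library 1 (0.060) or CyrKO library 2 (0.99, median -0.01). CyrKO library 2 of striatum/thalamus had a list mean of 5.11 (log2 CPM), against 3.74 to 4.21 in the other CyrKO libraries, and was also the library highest in striatum marker genes (7.18, against 5.31 to 6.49).

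Interferon response genes were higher in hippocampus and islets. In hippocampus 8 of 11 members were higher with a median of 0.25, and 2 were called adjusted over the list alone, the antiviral genes Ifit1 (1.69 to 3.02 CPM, n = 6 and 4) and Bst2 (2.90 to 4.93 CPM). In islets 8 of 8 were higher with a median of 0.17, with Ifit1 at 4.00 CPM in WT and 5.65 CPM in CyrKO (n = 4 and 4). Camera gave adjusted p of 4.1e-04 and 0.0011, and both were 0.755 with an estimated correlation. Both calls were kept without each library, with a median of 0.15 in hippocampus without CyrKO library 2. In cerebellum 10 of 10 were called higher (median 0.25; adjusted p = 0.761 with an estimated correlation), which ended without WT library 5 (0.38) or CyrKO library 3 (0.18). In pituitary 15 of 16 were called higher (0.20; adjusted p = 0.829 with an estimated correlation), which ended without WT libraries 1 (0.072) or 2 (0.17) or CyrKO libraries 3 (0.75) or 4 (0.075). The median there ranged from 0.048 to 0.33 over the libraries left out, and was 0.33 and 0.32 without CyrKO libraries 1 and 2.

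In spleen, genes of neutrophils and monocytes and of macrophages were lower. All 11 measured neutrophil and monocyte genes were lower in CyrKO, with a median of -0.86 and 4 called adjusted over the list alone. These were the resistin-like gene Retnlg (40.1 ± 15.1 to 12.5 ± 5.53 CPM, SD, n = 4 and 4), the monocyte surface gene Ly6c2 (71.2 ± 10.3 to 46.6 ± 4.06 CPM), the calprotectin subunit S100a8 (368 ± 226 to 134 ± 64.1 CPM) and the gelatinase Mmp9 (51.3 to 29.8 CPM). Of 12 macrophage genes 11 were lower, with a median of -0.35 and 4 called adjusted over the list alone. Among these were Cd68 (146 ± 17.4 to 110 ± 9.44 CPM) and the signalling adaptor Tyrobp (278 to 197 CPM). Camera gave adjusted p of 1.4e-08 and 3.6e-05, each 0.755 with an estimated correlation, and exact permutation p were 0.11 and 0.029. Both calls were kept without each library, with medians for the neutrophil list of -0.54 without WT library 1 and -1.52 without CyrKO library 3.

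Microglia and macrophage genes were instead called higher in cerebellum, striatum/thalamus and skeletal muscle. The adjusted p were 0.761, 0.776 and 0.816 with an estimated correlation. In cerebellum 10 of 12 were higher, such as the complement gene C1qa (13.7 to 19.3 CPM, n = 5 and 5), with a median of 0.18. The call there ended without CyrKO library 5 (camera adjusted p = 0.15), and the median was 0.28 without CyrKO library 1. In striatum/thalamus 12 of 13 were higher (0.10), ended without WT libraries 3 (0.071) or 5 (0.080), with a median of 0.17 without WT library 1. In skeletal muscle 9 of 9 were higher (0.26), ended without WT libraries 4, 5 or 6 or CyrKO libraries 1, 4 or 5 (0.056 to 0.42), with a median of 0.09 without CyrKO library 4.

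Circadian clock genes were lower in pituitary, where 13 of 18 were lower with a median of -0.41. The repressor Ciart went from 10.9 ± 6.64 to 4.31 ± 1.89 CPM and the output factor Dbp from 101 ± 46.7 to 48.1 ± 20.4 CPM (SD, n = 5 and 4), while the activator Npas2 went from 3.14 to 6.63 CPM. Camera gave an adjusted p of 0.0013 (adjusted p = 0.755 with an estimated correlation; exact permutation p = 0.048), and the call was kept without each library. By edgeR 0 members were called over all genes or adjusted over the list alone, with 10 at an unadjusted p under 0.05. In cortex 13 of 17 were lower with a median of -0.10 and 5 called adjusted over the list alone, among them Ciart (14.8 ± 1.86 to 9.94 ± 1.35 CPM, n = 4 and 4) and Cry2 (189 to 164 CPM). Camera gave 0.012 there (adjusted p = 0.755 with an estimated correlation), and the call ended without WT library 4 (0.071) or CyrKO library 1 (0.21, median -0.02).

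Cholesterol synthesis genes were lower in islets, 16 of 18 with a median of -0.14. Hmgcs1, an early enzyme of the pathway, was at 34.1 CPM in WT and 27.6 CPM in CyrKO (n = 4 and 4). Camera gave an adjusted p of 3.8e-04 (adjusted p = 0.755 with an estimated correlation), kept without each library (median -0.09 without CyrKO library 4). In spleen 16 of 18 were lower with a median of -0.13 (adjusted p = 0.755 with an estimated correlation), a call that ended without CyrKO library 2 (0.057). In brown adipose tissue 14 of 19 were higher with a median of 0.45, such as the squalene epoxidase Sqle (18.8 to 36.1 CPM, n = 5 and 5). That call (adjusted p = 0.816 with an estimated correlation) ended without WT library 2 (0.072), and the median was 0.24 without CyrKO library 5. Glucocorticoid response genes were higher in islets, 11 of 11 with a median of 0.26, such as the cell cycle inhibitor Cdkn1a (51.9 to 66.8 CPM). That call (adjusted p = 0.761 with an estimated correlation) ended without WT library 2 (0.071) or CyrKO library 4 (0.43).

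Markers of neighbouring tissue were called by camera in several tissues. In brown adipose tissue 14 of 14 fast muscle fibre genes were higher in CyrKO with a median of 1.74, such as the myosin heavy chain Myh1 (23.8 ± 21.6 to 139 ± 96.9 CPM, SD, n = 5 and 5). Camera gave an adjusted p of 4.5e-07 (adjusted p = 0.761 with an estimated correlation; exact permutation p = 0.079). The mean log2 CPM of the list was 2.19, 5.60, 6.52, 6.35 and -1.06 in the WT libraries and 6.96, 7.41, 8.37, 6.75 and 5.15 in the CyrKO libraries. In cerebellum 13 of 13 choroid plexus and ependyma genes were lower with a median of -0.77, such as Clic6 (42.0 to 27.3 CPM, n = 5 and 5; camera adjusted p = 1.0e-08, adjusted p = 0.755 with an estimated correlation; exact permutation p = 0.13). The mean log2 CPM of that list was 4.43 to 5.47 in WT, 2.59 and 1.95 in CyrKO libraries 1 and 5, and 3.92 to 5.08 in CyrKO libraries 2 to 4. Of 7 blood genes 6 were higher there with a median of 0.92, and the red cell anion exchanger Slc4a1 (1.47 to 7.34 CPM) was called adjusted over the list alone (camera adjusted p = 0.0039, adjusted p = 0.755 with an estimated correlation; exact permutation p = 0.14). In hippocampus 11 of 12 meninges and fibroblast genes were higher with a median of 0.51, such as the growth factor Igf2 (73.2 to 139 CPM, n = 6 and 4; camera adjusted p = 8.2e-04, adjusted p = 0.776 with an estimated correlation; exact permutation p = 0.25). These 4 calls were kept without each library, but the median of choroid plexus genes was -0.50 without CyrKO library 5. That of blood genes was 1.40 without WT library 3 and 0.60 without CyrKO library 2, and that of meninges genes was 0.34, 0.31 and 0.29 without WT libraries 1 and 5 and CyrKO library 1.

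In striatum/thalamus 13 of 13 striatum marker genes were higher with a median of 0.45. Among them were the adenosine receptor Adora2a (3.23 ± 0.73 to 19.96 ± 26.2 CPM, SD, n = 5 and 5) and the signalling protein Ppp1r1b (43.6 to 110 CPM). Of the list, 7 were at an unadjusted p under 0.05 and 0 were called by edgeR over all genes or adjusted over the list alone. Camera gave an adjusted p of 9.3e-05 (adjusted p = 0.761 with an estimated correlation; exact permutation p = 0.40). The list's mean log2 CPM was 5.37 to 5.47 in WT, 6.49 and 7.18 in CyrKO libraries 1 and 2, and 5.38, 5.31 and 5.37 in CyrKO libraries 3 to 5. Without CyrKO library 2 the median was 0.19 (camera adjusted p = 0.024).

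In hippocampus 7 of 7 choroid plexus and ependyma genes were higher with a median of 1.97, and 6 were called adjusted over the list alone. They were led by the thyroid hormone carrier Ttr (14.2 ± 7.94 to 1017 ± 2012 CPM, SD, n = 6 and 4). Camera gave an adjusted p of 0.0023 (adjusted p = 0.761 with an estimated correlation). CyrKO library 2 had a list mean of 7.10 (log2 CPM), against 3.48, 3.01 and 3.13 in the other CyrKO libraries and 2.63 to 3.55 in WT. Without it the median of the same 7 genes was -0.030 and the call ended (camera adjusted p = 0.72).

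**Figure D5:**
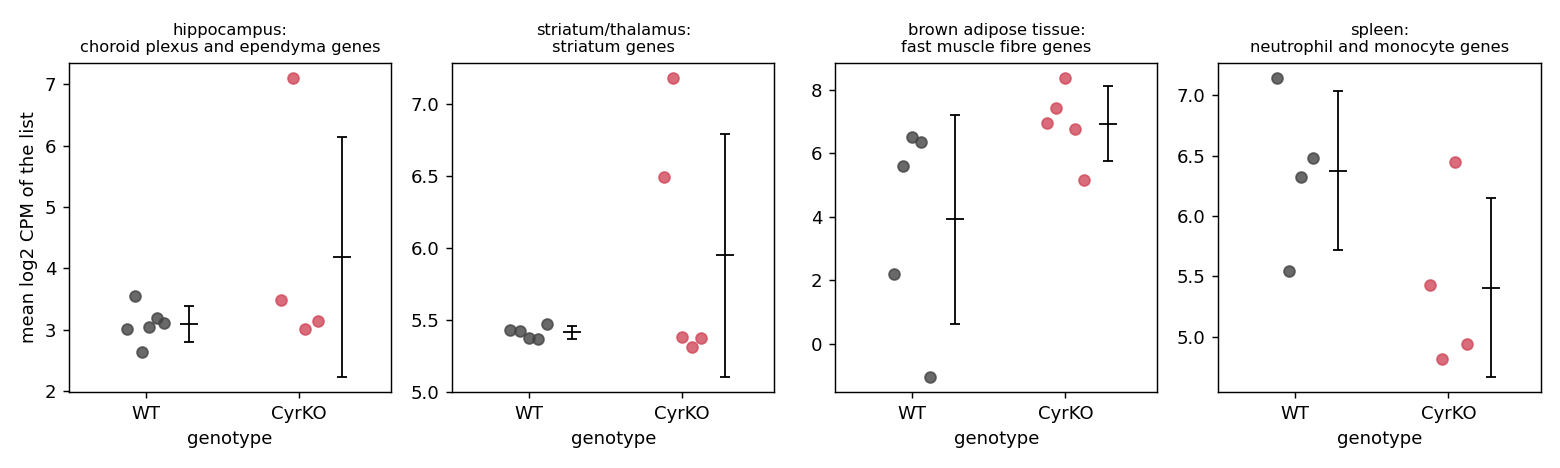
Mean log2 CPM of a gene list in each library, with WT in grey, CyrKO in red and black bars for the mean and SD, for choroid plexus genes in hippocampus, striatum genes in striatum/thalamus, fast muscle fibre genes in brown adipose tissue, and neutrophil and monocyte genes in spleen. In hippocampus 1 CyrKO library lies at 7.10 while the other CyrKO libraries lie at 3.01 to 3.48.

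In anterior cortex 10 of 13 GABAergic neuron genes were higher with a median of 0.12, and 2 were called adjusted over the list alone. The members with the lowest p included the interneuron factor Dlx1 (44.6 ± 15.5 to 89.4 ± 29.7 CPM, SD, n = 5 and 5), the calcium buffer Calb2 (28.5 ± 23.4 to 90.3 ± 42.4 CPM) and the GABA-synthesizing enzyme Gad1 (381 ± 103 to 586 ± 172 CPM). Camera gave an adjusted p of 0.022 (adjusted p = 0.755 with an estimated correlation). The call ended without CyrKO library 3 (0.15), and the median was 0.08 without WT library 4 and 0.19 without CyrKO library 2. The list of genes around Oip5os1 was called higher in brown adipose tissue, 10 of 15 with a median of 0.08, where Nusap1 was called over all genes (camera adjusted p = 0.013, adjusted p = 0.755 with an estimated correlation; median 0.02 without WT library 2).

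Calls on other cell type markers ended without several libraries each and had adjusted p of 0.761 to 0.816 with an estimated correlation. In cortex, astrocyte genes (12 of 14 higher) were not called without WT libraries 1 or 4 or CyrKO libraries 2 or 3 (camera adjusted p of 0.059 to 0.13). Cortical layer genes there (12 of 15 lower) were not called without WT libraries 1, 3 or 4 or CyrKO libraries 1, 2 or 3 (0.065 to 0.29). Neuron genes in hippocampus (12 of 14 lower, median -0.05) were not called without WT libraries 3, 4 or 6 or CyrKO libraries 1, 2 or 3 (0.054 to 0.64), and without CyrKO library 2 their median was 0.0014. In brown adipose tissue, meninges and fibroblast genes (9 of 9 lower, -0.27) were not called without WT libraries 2, 3 or 4 or CyrKO libraries 1, 4 or 5 (0.054 to 0.18). Blood genes there (7 of 7 lower, -1.12) were not called without WT libraries 1 to 4 or CyrKO libraries 1, 4 or 5 (0.052 to 0.17). The 23 lists called in no tissue include oligodendrocyte, endothelium, brown fat thermogenesis (6 members higher and 8 lower), beta cell, pituitary hormone and proliferation genes.

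RNA integrity and sequencing depth can shift gene levels and were compared between genotypes. In spleen all 5 CyrKO libraries of the labels were used, 1 of which has no counts. Neither RIN (adjusted p = 0.943, exact permutation tests over 10 tissues, two-sided) nor read number (lowest adjusted p = 0.397) differed detectably after adjustment. The lowest unadjusted value was in cerebellum, where WT libraries had 17.3 ± 2.1 and CyrKO libraries 13.1 ± 2.7 in units of 1000000 reads (SD, n = 5 and 5, exact permutation p = 0.048).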

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

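Of the tests in this part, that of other divisions of the libraries was set before its result was seen. The test of linked sequence was planned for called genes near the locus. Its form here, with an unadjusted p and without Oip5os1, Nusap1 and Oip5, was fixed after those genes were seen to change. Tests of the genotype labels in the miR-7 comparison, of divisions without Oip5os1 and of dividing cells were chosen after the result was seen. So were those of transcripts running on, of choroid plexus in 1 library, of 3′ UTR trends and of miR-7 site strength.

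Nusap1 was higher in CyrKO in 10 of 10 tissues and passed in 5, next to the deleted gene. More dividing cells would raise other mitotic genes with it, but in brown adipose tissue the median log2 fold change of 6 proliferation genes was -0.027 (95% bootstrap interval -0.26 to 0.44) against 5.80 for Nusap1, and that of the 3 measurable ones in skeletal muscle was 0.048 (-0.08 to 0.56) against 5.56, which argues against dividing cells as the source in both. If linked 129S6 sequence shifted many genes of the region, genes within 10 Mb would more often have an unadjusted p under 0.05, and the odds ratio was 0.944 in skeletal muscle (Fisher's exact test, 0.42 to 1.86) and 1.48 in brown adipose tissue (0.84 to 2.45), intervals that leave such a shift, as well as a variant at Nusap1 itself, open. Transcripts running on from the altered locus into Nusap1 may also contribute: the gain in Nusap1 CPM was at most 0.308 of the WT level of Oip5os1, in brown adipose tissue, and counts per gene without strand cannot tell such reads from a normal Nusap1 transcript. A direct effect of the loss of Cyrano on its neighbour stays open and untested, since all CyrKO mice carry the same altered locus.

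Choroid plexus and ependyma genes stood out in hippocampus because CyrKO library 2 had a list mean of 7.10 (log2 CPM) and the other CyrKO libraries 3.01 to 3.48. Without it the median log2 fold change of the 7 genes was -0.030 instead of 1.97 (Ttr from 6.16 to -0.40, Enpp2 from 2.02 to -0.03, Kl from 1.45 to 0.12, Foxj1 from 0.79 to 0.19, Clic6 from 4.62 to 1.16), which follows in part from leaving out the highest library. Loss of Cyrano raising these genes in each animal does not account for it, since 3 of the 4 CyrKO libraries lay at or below the highest WT library. Choroid plexus tissue in that library is a candidate source: the 20 genes outside the list that best followed it over 19 WT libraries of the other 4 brain regions were higher there than in the other CyrKO libraries of hippocampus, by a median of 3.27 on the log2 scale (95% bootstrap interval 2.33 to 4.28). Whether such tissue was carried in at dissection or was more abundant in that animal stays open.

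Genes with a miR-7 site were lower than matched genes in 5 tissues, by -0.011 to -0.026. A trend with UTR length or base content alone does not account for the shift in skeletal muscle, where after removal of such trends GTCTTCC was among the lowest 0.00643% of 7-base words. More miR-7 activity would shift 8mer sites more than weaker 7mer sites, which held in 4 of the 5 tissues (spleen being the exception, -0.024 and -0.026). Chance differences between libraries stay open in brown adipose tissue, hippocampus, skeletal muscle and spleen, where exact permutation of the genotype labels gave p of 0.0873, 0.290, 0.0823 and 0.371, and striatum/thalamus, at 0.0238, did not pass over the 10 tissues (0.24). A second permutation, of the trend-corrected word score and chosen after the first was seen, gave p = 0.0043 in skeletal muscle (0.043 over the 10 tissues), so that an increase in miR-7 activity there is a hypothesis consistent with part of these tests, while 9 of 20 literature targets of miR-7 were lower there.

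The number of called genes was compared over divisions of the same libraries into groups of the same sizes, at most 100 per tissue with the real division counted among them. As many genes were called in 1 of 100 divisions in brown adipose tissue (real 3, highest other 1), 2 of 100 in cerebellum (2, 34), 2 of 100 in hippocampus (2, 18), 4 of 100 in skeletal muscle (3, 19) 3 of 100 in striatum/thalamus (2, 38) and 2 of 35 in cortex (2, 151), but each real number includes Oip5os1, the deleted gene, which divisions that mix the genotypes are unlikely to call. In anterior cortex (4 of 100; 1, 31), islets (5 of 35; 1, 196), pituitary (6 of 100; 1, 563) and spleen (6 of 35; 1, 63) the 1 call is Oip5os1, so the number says nothing of other genes. With Oip5os1 left out before adjustment in every division, as many genes were called in 2 of 100 divisions in brown adipose tissue (real 1, highest other 1) and 4 of 100 in hippocampus (1, 18). The share was 5 of 100 in skeletal muscle (2, 19), 7 of 100 in striatum/thalamus (1, 38) and 2 of 35 in cortex (1, 151), while in cerebellum 0 genes were called. These shares rest on 1 or 2 genes per tissue and are not adjusted over tissues, so they do not exclude chance in any of them. With genes within 10 Mb left out edgeR called 1 gene in skeletal muscle and 0 in each of the other 9 tissues. By the share of genes at an unadjusted p under 0.05, 6 of 100 divisions in brown adipose tissue, 21 in anterior cortex, 22 in skeletal muscle, 49 in pituitary, 51 in hippocampus, 66 in striatum/thalamus and 70 in cerebellum were as large, as were 13 of 35 in spleen, 23 in islets and 28 in cortex, so chance was not excluded by that share in any tissue. Outside brown adipose tissue some divisions called many times more genes than the real one, and what sets those libraries apart was not tested.

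The effect of genotype differed between tissues for Oip5os1 (F = 56.6), Nusap1 (53.8), Oip5 (7.44) and Nrep (4.74), as tested by interaction. For Cdr1 the interaction over the 10 tissues did not pass (F = 3.37, edgeR adjusted p = 0.175), and in pairs tested because it was called in cerebellum its log2 change there differed from that in anterior cortex by -2.10, in cortex by -1.33, in hippocampus by -1.73 and in striatum/thalamus by -1.65.

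Single libraries lay far from the rest of their group in 18 of 214 groups examined (Dixon's test at 95%), where chance gives about 1 in 20, or 10.7. By RIN these were WT cortex library 3 (8.6, others 9.2 to 9.3), WT islets library 1 (8.1, others 7.4 to 7.5) and WT pituitary library 3 (6.6, others 9.3 to 9.6). By reads they were WT hippocampus library 4 (23.8, others 11.5 to 15.6, in units of 1000000 reads) and WT striatum/thalamus library 1 (9.77, others 11.8 to 12.4). By total counts, in units of 1000000, they were the same 2 libraries (16.6, others 8.03 to 10.9, and 7.05, others 8.33 to 8.72) and WT spleen library 4 (9.74, others 5.72 to 6.32). Oip5os1 was lower (log2 CPM) in WT anterior cortex library 2 (8.02, others 9.09 to 9.45), WT hippocampus library 2 (7.85, others 8.65 to 8.91) and CyrKO striatum/thalamus library 2 (4.52, others 4.68 to 4.73). Nusap1 was higher in WT hippocampus library 2 (3.13, others 1.72 to 2.18), and Nrep in WT cerebellum library 5 (10.11, others 9.59 to 9.72) and WT striatum/thalamus library 5 (6.34, others 5.89 to 5.95). WT library 2 thus stood out for both Oip5os1 and Nusap1 in hippocampus and for Oip5os1 in anterior cortex. Nusap1 also passed without WT library 2 in anterior cortex, cerebellum and pituitary. Whether that number marks 1 animal is not given by the labels, and the cause was not tested. By list mean the others were blood genes in WT brown adipose tissue library 5 (0.32, others 3.62 to 4.61), cholesterol synthesis genes in CyrKO brown adipose tissue library 5 (5.75, others 4.98 to 5.19) and microglia genes in WT cerebellum library 2 (3.32, others 3.62 to 3.71).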

How the results depend on the processing

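Alternatives added after seeing the data were the label permutations of lists and sites, sites of 7 bases without an 8mer, camera on site genes, libraries left out in list and site tests, and Oip5os1 left out near the locus or before adjustment. Oip5os1 kept its direction and call in the 10 tissues under each alternative run there that left it among the genes tested; RIN and the replicate block were run in 8 tissues. Nusap1 in its 5 tissues and Nrep in skeletal muscle kept theirs under the alternatives run for them. Of the results that answer a comparison, 726 values stayed on the same side of their threshold or within their spread, 48 moved, 37 reversed, 14 became stronger and 17 weaker; of single genes 415 stayed, 7 reversed, 9 became stronger and 20 weaker. Depth limits the fold change of Oip5 in brown adipose tissue, at 0.182 CPM in WT. Where no reason is given, the cause was not tested.

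Counts of called genes were higher with DESeq2, at 37 in anterior cortex, 63 in brown adipose tissue, 3 in islets, 3 in pituitary, 6 in skeletal muscle and 15 in spleen. With genes within 10 Mb of Oip5os1 left out, edgeR called 1 gene in skeletal muscle and 0 in each of the other 9 tissues, and 0 genes in several tissues, because Oip5os1 and its neighbours are the genes removed; Cdr1 in cerebellum then had an adjusted p of 0.076. With Oip5os1 alone left out before adjustment edgeR called 1 gene in brown adipose tissue, cortex, hippocampus and striatum/thalamus, 2 in skeletal muscle and 0 in anterior cortex, cerebellum, islets, pituitary and spleen, because 1 gene is removed and the adjustment of the others gets stricter. With RIN as a covariate the count was 1 in cerebellum, and the log2 fold change of Nrep in hippocampus was 0.023 instead of -0.08. Leaving Oip5os1 out of the near-locus test gave counts of 0 near genes in anterior cortex, cerebellum, islets, pituitary and spleen, by construction. Of the 38 list calls, 0 passed with an estimated correlation and 0 by exact label permutation, and 30 of 154 pairs passed with a mean count of at least 100. Exact label permutation has too few divisions for any list to pass alone.

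The replicate number was not taken to pair WT and CyrKO libraries, by a rule that every pair correlate above 0.1. Of 8 tissues 0 met it (lowest r per tissue -0.21 to 0.069). That rule cannot exclude a pairing or a batch behind the numbers. In cortex each library correlated best with its own number, a hint from the data and not from the design. Each WT library with a same-numbered CyrKO library did so in hippocampus, some did in other tissues, and none did in islets. With the replicate number as a block, edgeR called 15 genes in brown adipose tissue, and Cdr1 passed in cortex (0.011); no other count moved by over 1.5 times. In skeletal muscle and spleen neither a replicate block nor RIN was fitted, because the numbers in the column names could not be matched to the replicate numbers of the labels. Tests on the authors' p-values were not run, because counts were at hand.

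The miR-7 shift in the medians depended on the matching. Matched on expression only, it was -0.0266 in anterior cortex, 0.0065 in brown adipose tissue, -0.0022 in cerebellum, 0.0019 in hippocampus, -0.025 in pituitary and 0.031 in spleen, all opposite in sign to the values with UTR length matched; of these anterior cortex, pituitary and spleen passed, as did cortex (-0.0077) and islets (-0.0192). Matched on GC content also, it was -0.0060 in anterior cortex, -0.0084 in cerebellum and -0.0013 in pituitary, again opposite in sign, passed in cerebellum and in islets (-0.0149), and was -0.0136 in spleen and -0.0064 in striatum/thalamus. With 7mer-A1 sites added it passed in cortex (-0.0038). Sites of 7 bases without an 8mer gave 0.0137 in anterior cortex, which passed (0.019) in the direction opposite to more miR-7 activity while the main value there (0.0086) did not pass; they gave 0.00019 in islets and -0.0083 in skeletal muscle, where the call ended (0.10). Sites of 8 bases alone gave -0.0012 in cerebellum and -0.0173 in islets, which passed there (resampling over genes, adjusted p = 0.027). The shortest 3′ UTR gave -0.0032 in cerebellum. Under exact permutation of genotype labels the shifts of -0.0186 in brown adipose tissue, -0.0103 in hippocampus, -0.0148 in skeletal muscle, -0.0212 in spleen and -0.0123 in striatum/thalamus no longer passed, because libraries rather than genes are then the units. The trend-corrected word score was -0.411 in anterior cortex, -2.27 in cerebellum and -0.0574 in pituitary, opposite in sign to the median differences there. By exact label permutation it passed in skeletal muscle (-4.86). It did not pass at -3.07 in brown adipose tissue, -2.44 in hippocampus, -3.50 in spleen or -3.99 in striatum/thalamus. Skeletal muscle has 924 divisions of its labels, brown adipose tissue and striatum/thalamus 252, hippocampus 210 and spleen 70. Fewer divisions limit how low p can go. In spleen the real division had the lowest score, the next lowest being -2.82 (exact permutation p = 0.029, adjusted p = 0.095). Not passing in those tissues therefore does not show that the signal is absent there.

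With each library left out in turn, counts of called genes ranged from 1 to 7 in anterior cortex, 1 to 2 in cerebellum, 2 to 4 in hippocampus, 1 to 18 in islets, 1 to 2 in pituitary, 3 to 6 in skeletal muscle, 1 to 6 in spleen and 2 to 4 in striatum/thalamus. Log2 fold changes crossed 0 for Nrep in hippocampus (-0.20 to 0.0062), Cdr1 in pituitary (-0.86 to 1.02), Nusap1 in spleen (-0.023 to 0.37) and Oip5 in spleen (-0.40 to 0.15), none of which was called. The miR-7 shift ranged from 0.0032 to 0.0159 in anterior cortex, -0.0253 to -0.0137 in brown adipose tissue, -0.0055 to 0.0064 in cerebellum, -0.0052 to 0.0014 in cortex, -0.0122 to -0.0031 in hippocampus, -0.0085 to 0.0012 in islets and -0.0085 to 0.0137 in pituitary. The difference in RIN (CyrKO minus WT) ranged from -0.04 to 0.235 in anterior cortex, -0.0917 to 0.267 in cortex, -0.025 to 0.208 in islets, -0.075 to 0.675 in pituitary, -0.29 to 0.0867 in skeletal muscle and -0.27 to 0.18 in striatum/thalamus, and that in reads (units of 1000000) from -1.23 to 0.249 in cortex, -1.63 to 0.704 in skeletal muscle and -0.843 to 3.22 in spleen. The spleen values use the 5 CyrKO libraries of the labels.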

Other observations

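The tests in this part were all chosen after the result was seen, and the genes were named after their values were seen.

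Serpina3n, a secreted serine protease inhibitor that reactive astrocytes make, was higher in CyrKO in 7 tissues at an unadjusted p under 0.05, without passing adjustment in any by edgeR. In anterior cortex it was at 21.8 ± 24.5 CPM in WT and 71.8 ± 5.70 CPM in CyrKO (SD, n = 5 and 5; log2 fold change 1.76 ± 0.46), in hippocampus at 68.5 ± 36.0 and 148 ± 10.5 CPM (n = 6 and 4; 1.13 ± 0.24), and in cerebellum at 7.73 ± 11.9 and 30.8 ± 2.88 CPM (n = 5 and 5; 1.97 ± 0.61). The mean effect over the 5 brain regions was taken from the edgeR model of all libraries of the 10 tissues. By that mean Serpina3n was 1.48 ± 0.20 higher (edgeR, Benjamini-Hochberg adjusted p = 7.8e-07). Its paralogs Serpina3f (2.56 ± 0.36, 3.5e-06), Serpina3m (2.41 ± 0.43, 9.4e-04) and Serpina3c (1.82 ± 0.35, 0.0025) were higher as well. Reads of such near-identical genes can be split wrongly between them. By the same mean over brain regions Cdr1 was lower (-1.14 ± 0.16, 7.5e-06), and Nrep was at -0.07 (0.94). The nuclear import receptor Ipo11 (-0.22 ± 0.03, 7.5e-06) and the pseudouridine synthase Trub1 (-0.32 ± 0.07, 0.0064) were lower too. If regions came from the same animals, their libraries are not independent and these p-values are too small.

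Ciart, a repressor of the circadian clock, was lower in 7 tissues at an unadjusted p under 0.05 (log2 fold change -0.38 in striatum/thalamus to -1.35 in pituitary), and the clock output gene Dbp in 4, whereas Arntl, the activator of the opposite phase, was higher in 4. The chaperone Hsph1, the co-chaperone Stip1, the class I antigen gene H2-K1, the interferon regulatory factor Irf3 and the endothelial tight junction gene Cldn5 were higher in 5 tissues each. Of all genes, 70 were higher and 54 lower in at least 3 tissues at an unadjusted p under 0.05, where independent tissues would give 14.1 and 10.5, and 9 were higher and 3 lower in at least 5, where they would give 0.0110 and 0.00667. Time of death, which the labels do not give, was not tested.

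Libraries of different tissues with the same number may come from the same animal, a hypothesis that the labels leave open. Over the 60 most variable genes, anterior cortex and cerebellum libraries of the same number deviated together from their group means (mean r = 0.615 in WT and 0.370 in CyrKO), and each of 5 libraries in both genotypes matched its own number best. The exact permutation p was 0.00833 in each genotype, the smallest that 120 numberings can give. Over 56 such tests it was 0.233 after adjustment, and of the 8 tests with an unadjusted p under 0.05, 0 passed. With so few numberings, a pass over 56 tests needs many of them at their smallest p. Not passing therefore does not decide whether the numbers mark animals. If the numbers do mark animals, similar shifts in several brain regions are in part repeated measures of the same mice.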
